A study of Mus musculus with 8 samples.

How the data were processed

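ATAC-seq libraries were made from YFP-positive mouse liver cells isolated by flow cytometry, per the labels' protocols, and the series covers early and macroscopic liver lesions of an Rb family triple knockout model. The submitters' processing notes name Bowtie 1.1.2, MACS2, HOMER and deepTools and the genome build mm10, without the role or order of each tool, and versions other than Bowtie's are not given in the sources used here. Neither the labels nor the files say whether libraries of a group were pooled before peak calling, whether reads were shifted for the transposase offset, or how duplicate and mitochondrial reads were treated. All 5 lists are in the narrowPeak layout that MACS2 writes. In that layout the deposited signal value is a fold enrichment, a linear ratio, and the deposited columns of significance are −log10 p and −log10 q values. The lowest deposited −log10 q in the 5 lists was 1.30 to 1.32, the value of a q of 0.05. These fold and −log10 values are the authors' and were used only to rank or filter peaks within their own list. The share of peaks with −log10 q of 5 or more ranged from 70.8% (Tumor Sox9) to 92.4% (Prog-like CK19), and median widths from 349 bp (EpCAM-high Sox9) to 520 bp (Prog-like CK19). A deeper library gives more peaks at the same threshold, so list length mixes depth and biology. Lists were therefore also compared at 39644 peaks each, the length of the shortest, taken by −log10 p.

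The EpCAM-high lists were tied to 2 of the 5 sample groups by name. The Prog-like and Tumor lists were tied to no group, and no list was used as a replicate of another. For each pair, overlapping peaks were merged into regions, and the share of regions holding a peak of both lists was computed with a minimum overlap of 1 bp. The chance level was taken from 20 random circular shifts of 1 list along each chromosome, a comparison added after seeing the data. The shifts do not keep peaks at gene ends, so a share above this level does not by itself show that the cells are alike. Gene positions were those of the RefSeq annotation of GRCm38.p6, the same build as mm10, for 21887 protein-coding genes. The annotation table used here gives gene starts and ends but no strand, transcripts or exons. The planned count of peaks at promoters was therefore replaced by a count of peaks within 1000 bp of either gene end, so that a gene-end peak can lie at the start or at the end of transcription, and exons and introns were not separated. The planned scan for 20 transcription factor motifs was not run, because no genome sequence was used here. Locus peaks are peaks that overlap the gene body or 10 kb on either side.

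Before the data were examined, 17 gene lists with 310 genes were fixed: biliary and progenitor, hepatocyte, oncofetal, mesenchymal and stellate, sort markers, blood cell, endothelial, E2F and cell cycle, Rb family, Notch, Wnt, YAP and Hippo, TGF-beta, inflammation, cancer stem cell, housekeeping and other tissue. All symbols matched the annotation. For each list and pair, the median difference in locus peaks was placed as a percentile among 10000 random lists of the same size, drawn from protein-coding genes in 10 bins of total locus peaks (seed 1). A percentile describes these peak lists and is not a test, since genes are not replicates. After the first results, 6 further lists (74 genes) of macrophage, T and NK, B and plasma, neutrophil, dendritic, and erythroid and megakaryocyte genes were added for the closing observations. Also added after seeing the data were the mean difference of each list and the percentile of its gene-end difference.

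Genes were named by a rule fixed before the data were examined. For each of the 6 pairs it took (a) up to 20 list genes with a gene-end peak in 1 peak list and not in the other, both as deposited and at equal length, in order of their difference in locus peaks. It also took (b) the 5 protein-coding genes per direction with the largest difference in locus peaks at equal length, and (c) the 3 regions per direction with the highest −log10 q in 1 list that overlapped no peak of the other. Part (a) counted 58 genes for the CK19 and 65 for the Sox9 comparison of Prog-like with EpCAM-high, 73 for Tumor with Prog-like and 47 for Tumor with EpCAM-high. Of the genes that part (a) named, 2 are not reported here. Part (b) counts peaks and so favours long genes. Thy1, Epcam, Krt19, Sox9, Rb1, Rbl1, Rbl2, Alb, Hnf4a, Afp, Ptprc, Cd3e, Col1a1 and Pecam1 were named whatever their values. Pcna and Mcm2 were named as examples after their values were seen.

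The alternatives tried were equal list length, a −log10 q of 5 or more, autosomes alone, an overlap of at least 50% of either peak, a gene-end window of 2500 bp and loci with 50 kb flanks. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. Neighbouring peaks and genes are not independent, so true uncertainty is wider. The overlap calculation and the percentile of the mean difference were tested on simulated data, the latter for 1 pair and 1 list size. The percentiles of median differences given in the results were not tested in this way. For the comparison of Prog-like with EpCAM-high CK19 over 21887 genes, 2.5% of 200 random lists of 25 genes fell outside percentiles 2.5 to 97.5 of the mean difference, and 96.0% of 50 lists given 3 added peaks per gene stood above percentile 97.5. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on unplaced contigs entered the overlaps and were assigned to no gene.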

Results

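Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in liver cells of a mouse model of liver cancer in which the retinoblastoma (Rb) gene family is deleted. The labels list 8 samples in 5 groups: EpCAM-high cells of a CK19 set (2 samples) and of a Sox9 set (1 sample), Thy1-positive cells of a CK19 set (2 samples) and of a Sox9 set (1 sample), and EpCAM-negative cells (2 samples). Cells came from liver tissue or from visible lesions and were sorted for YFP, which marks Cre recombination, and by the surface proteins Thy1 and EpCAM. CK19 (gene Krt19) and Sox9 are markers of bile duct and progenitor cells, and the labels do not state what they stand for in the sample names. The values analysed were 5 peak lists, each for 1 condition: EpCAM-high CK19, EpCAM-high Sox9, Prog-like CK19, Prog-like Sox9 and Tumor Sox9. The EpCAM-high lists carry the names of 2 sample groups, whereas no label uses the names of the other 3 lists. Those are compared under the authors' names and assigned to no sorted group. Read depth is unknown. With 1 list per condition there is no replicate error and no test between conditions, and every interval below is an exact (Clopper-Pearson) 95% binomial interval that covers counting error only.

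The lists held 56932 (EpCAM-high CK19), 59454 (EpCAM-high Sox9), 71375 (Prog-like CK19), 67855 (Prog-like Sox9) and 39644 (Tumor Sox9) peaks, covering 30.8, 26.4, 44.6, 33.7 and 24.3 Mb. The share of peaks within 1000 bp of either end of a protein-coding gene was 26.8% (26.4 to 27.3) in Tumor Sox9, 21.7% in each EpCAM-high list (21.4 to 22.1 in both) and 18.2% in each Prog-like list (17.9 to 18.5 in both). Peaks elsewhere in gene bodies made up 44.0% of Prog-like CK19 and 43.3% of Prog-like Sox9, against 34.1% of EpCAM-high CK19, 37.8% of EpCAM-high Sox9 and 33.3% of Tumor Sox9. The remaining 37.8% (Prog-like CK19) to 44.1% (EpCAM-high CK19) lay between genes.

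The genes named by the model were examined in every list before any comparison. Rb1 (chromosome 14, 73192858 to 73325951) and Rbl2 (chromosome 8, 91070057 to 91123844) had a peak at a gene end in all 5 lists, and Rbl1 (chromosome 2, 157145893 to 157204534) had one in the 2 CK19 lists as deposited and in no list at equal length. Within the gene and 10 kb on each side, Rb1 held 7 (EpCAM-high CK19), 6 (EpCAM-high Sox9), 19 (Prog-like CK19), 16 (Prog-like Sox9) and 6 (Tumor Sox9) peaks. In the same order Rbl1 held 1, 0, 7, 5 and 1 and Rbl2 held 3, 2, 8, 8 and 2. At equal length Rb1 held 5, 4, 8, 5 and 6, so that most of the Prog-like excess went, Rbl1 held 0, 0, 3, 1 and 1, and Rbl2 held 2, 2, 6, 6 and 2. A peak outside a deleted exon does not check a deletion, and the labels do not say which exons were removed. No list of cells with intact genes was used here. Genes driven by E2F, the transcription factor family that Rb proteins hold in check, had a gene-end peak at most members in every list. Of 29 members, 28, among them the S-phase genes Pcna and Mcm2, had a gene-end peak in every list except Prog-like Sox9, which had 27. At equal length the counts were 27, 27, 27, 23 and 28 in the order above. Over all protein-coding genes the share as deposited ran from 51.1% (Tumor Sox9) to 57.8% (EpCAM-high CK19). Housekeeping genes had gene-end peaks at 18, 18, 19, 19 and 17 of 20 members.

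The sorting marker Epcam (chromosome 17, 87635979 to 87651127) had a gene-end peak in all 5 lists as deposited, but in neither Prog-like list once the lists were reduced to 39644 peaks each. Thy1 (chromosome 9, 44043384 to 44048579) had no peak within 10 kb in any list, and the nearest peak lay 18196 to 18221 bp away in the 5 lists. Sox9 (chromosome 11, 112782210 to 112787757) held 4, 3, 1, 0 and 3 locus peaks in the order above, with no Prog-like peak left at equal length. The T-cell gene Cd3e held none in any list.

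**Figure D1:**
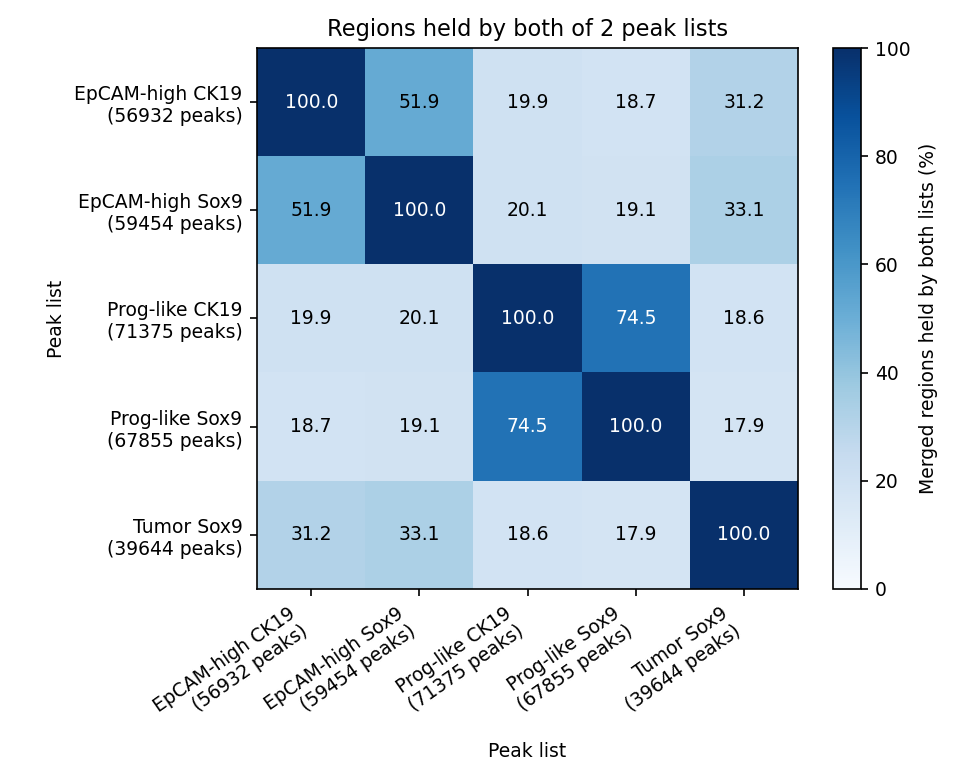
Percentage of merged regions held by both of 2 peak lists, for all 10 pairs of the 5 lists, with each list's number of peaks on both axes. The 2 Prog-like lists shared 74.5% of their regions and the 2 EpCAM-high lists 51.9%, whereas each Prog-like list shared between 17.9% and 20.1% with any EpCAM-high or Tumor list.

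The Prog-like and EpCAM-high lists were compared within the CK19 set and within the Sox9 set, to ask how accessible chromatin differed between the cells of these lists. Bile duct and progenitor genes had gene-end peaks in the EpCAM-high lists more often than in the Prog-like lists: all 23 members of the list had a gene-end peak in both EpCAM-high lists (100%, 85.2 to 100). In Prog-like CK19 9 members had one (39.1%, 19.7 to 61.5) and in Prog-like Sox9 6 (26.1%, 10.2 to 48.4). Krt19, the keratin of bile duct cells (chromosome 11, 100140810 to 100145926), held 4 and 6 peaks in the CK19 and Sox9 EpCAM-high lists and 0 in both Prog-like lists. The chloride channel gene Cftr (chromosome 6, 18170687 to 18322770) held 16 and 15 against 0 and 0. Blood-cell genes showed the opposite order, with a gene-end peak at 16 of 30 members in Prog-like CK19 (53.3%, 34.3 to 71.7) and 14 in Prog-like Sox9 (46.7%, 28.3 to 65.7). The EpCAM-high lists had one at 8 (26.7%, 12.3 to 45.9) and 7 (23.3%, 9.93 to 42.3). Over all protein-coding genes the share was 57.4% in Prog-like CK19, 54.4% in Prog-like Sox9, 57.8% in EpCAM-high CK19 and 57.7% in EpCAM-high Sox9. Blood-cell genes thus lay below the all-gene share in each of these lists. The Prog-like intervals held that share, and the EpCAM-high intervals lay under it. The pan-leukocyte gene Ptprc (chromosome 1, 138062859 to 138175756) held 13 and 14 peaks in the Prog-like lists and 3 and 2 in the EpCAM-high lists. It had a gene-end peak in each of these lists, so its gene-end call did not separate them.

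The median biliary gene held 3 fewer peaks in Prog-like than in EpCAM-high CK19 and 4 fewer in the Sox9 set, below all 10000 random gene lists matched on peak number in both sets (percentile 0.0). In the CK19 set the genes with a gene-end peak in EpCAM-high alone included Bicc1 (8 against 1 locus peaks), Krt23 (5 against 0), Dmbt1 (4 against 0), the Hippo pathway transcription factor gene Tead1 (9 against 3) and Reln (15 against 1). Pkhd1 and Zeb1 also had a gene-end peak in EpCAM-high CK19 alone, although their whole loci held more peaks in Prog-like CK19 (13 against 4 and 8 against 3). In the Sox9 set the corresponding genes were Bicc1 (12 against 1), Cdh1 (9 against 2), Krt23 (7 against 0), Aqp1 (5 against 0), Tead1 (18 against 3), Tead4 (9 against 0) and Cdh2 (12 against 1). They also included Hmga2 (8 against 3), the Wnt pathway genes Wnt7b (7 against 0) and Lgr5 (5 against 0), and Pdx1 (6 against 0).

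Macrophage genes were among the genes with a gene-end peak in the Prog-like lists alone. Adgre1, which encodes the macrophage surface protein F4/80 (chromosome 17, 57358581 to 57483529), held 8 locus peaks in Prog-like CK19 and 5 in Prog-like Sox9 against 0 in both EpCAM-high lists. The lysozyme gene Lyz2 held 6 and 5 against 0 and 0, and Laptm5 held 4 and 5 against 0 and 0. In the CK19 set the macrophage growth factor receptor gene Csf1r (8 against 0), Tnf (7 against 0), Ccl2 (4 against 0), Anpep (4 against 0), F9 (5 against 0), Vwf (11 against 5) and Reep5 (6 against 1) followed. In the Sox9 set the others were Zeb2 (22 against 7) and the endothelial receptor gene Kdr (5 against 0). The median blood-cell gene held 2 more peaks in Prog-like CK19 (percentile 100) and 1 more in Prog-like Sox9 (percentile 98.4). Inflammation genes had gene-end peaks at 16 and 14 of 20 members in the Prog-like lists against 10 and 13 in the EpCAM-high lists, an order that turned in the Sox9 set at equal length (10 against 12) and was 11 against 10 in the CK19 set. Endothelial genes had them at 6 and 4 of 15 against 2 and 2 (3 and 3 against 1 and 1 at equal length, 9 and 7 against 4 and 4 with a window of 2500 bp). Pecam1, the endothelial adhesion gene that many leukocytes also use, held 12 and 5 locus peaks against 1 and 2 (4 and 3 against 1 and 2 at equal length).

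Hepatocyte genes had gene-end peaks at 8 and 9 of 37 members in the Prog-like lists and at 17 and 20 in the EpCAM-high lists. Alb, which encodes albumin (chromosome 5, 90460870 to 90476602), held 0 and 0 peaks in the Prog-like lists and 1 and 3 in the EpCAM-high lists. Hnf4a, a regulator of hepatocyte identity (chromosome 2, 163506811 to 163572907), held 5 peaks in each of these 4 lists, with a gene-end peak in the EpCAM-high lists alone. A window of 2500 bp gave the Prog-like lists one too, beyond 163572907 (from 163575009 in CK19 and 163575015 in Sox9). At the other end the EpCAM-high lists held a peak from 163506485 (CK19) and 163506476 (Sox9). The nearest Prog-like peaks there began at 163515976 (CK19) and 163516471 (Sox9). Wnt pathway genes had gene-end peaks at 10 and 6 of 18 members in the Prog-like lists against 16 and 14, with the median difference in locus peaks at percentiles 0.28 (CK19) and 0.01 (Sox9). YAP and Hippo pathway genes had them at 11 and 9 of 14 against 13 and 13, with percentiles 0.04 and 0.105. Mesenchymal genes (12 and 11 of 24 against 14 and 12), Notch genes (12 and 11 of 16 against 13 and 12) and TGF-beta genes (13 and 12 of 15 against 11 and 10) differed by 2 members or fewer as deposited. At equal length Notch genes stood at 9 and 8 against 13 and 11. Col1a1, the type I collagen gene, held 1 and 0 locus peaks in the Prog-like lists and 3 and 5 in the EpCAM-high lists. Of the gene lists in this paragraph, TGF-beta genes alone had more members with a gene-end peak in the Prog-like lists, as blood-cell genes did. At equal length TGF-beta genes stood at 10 and 10 in the Prog-like lists against 9 and 8.

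The 5 protein-coding genes with the most added peaks at equal list length were long genes in each direction (median lengths 725 to 1106 kb, against 17.2 kb for all protein-coding genes). They were Exoc4 (24 against 1), Fmnl2 (21 against 0), Hdac9 (22 against 2), Dpp10 (19 against 0) and Itsn1 (19 against 1) in Prog-like CK19. In EpCAM-high CK19 they were Auts2 (35 against 0), Pde4d (44 against 14), Macrod2 (41 against 16), Esrrg (24 against 0) and Rbms3 (24 against 0). In the Sox9 set Dpp10 (26 against 5), Hdac9 (25 against 6), Immp2l (27 against 8), Slc8a1 (25 against 6) and Exoc4 (23 against 5) led in Prog-like. Etl4 (31 against 0), Pde4d (46 against 15), Auts2 (27 against 0), Syt1 (26 against 0) and Rbms3 (23 against 0) led in EpCAM-high. The region with the highest of the authors' −log10 q values in Prog-like CK19 that overlapped no EpCAM-high CK19 peak lay in Mroh2a (chromosome 1, 88226764 to 88227856; −log10 q 516), followed by regions nearest to Agtr1b and Robo2. Its counterpart in EpCAM-high CK19 lay between genes, nearest to Nrip1 (chromosome 16, 76242719 to 76243389; −log10 q 302), followed by regions in Mrc1 and nearest to Tcf4. In the Sox9 set these regions lay nearest to Aga (chromosome 8, 53496042 to 53496704; −log10 q 412) and 1700017N19Rik and in Cacna2d1 for Prog-like. For EpCAM-high they lay in Xkr4 (chromosome 1, 3514662 to 3515452; −log10 q 261), Adgrv1 and Dlg2.

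Across the genome, 19.9% of the merged regions were held by both CK19 lists (19.7 to 20.2) and 19.1% by both Sox9 lists (18.8 to 19.3). Sliding 1 list along each chromosome at random gave 1.42% and 1.15% on average. A gene-end peak in Prog-like alone was found at 1423 protein-coding genes in the CK19 set and 1242 in the Sox9 set, in EpCAM-high alone at 1520 and 1965, and in both at 11136 and 10666. The split of the CK19 counts depended on the threshold, at 1082 and 2205 genes with lists of equal length and 1582 and 1414 with peaks of −log10 q of 5 or more. At equal length the members with a gene-end peak in Prog-like CK19 and Sox9 were 2 and 2 for biliary, 3 and 3 for Wnt, 7 and 6 for YAP and Hippo, 4 and 6 for mesenchymal and 11 and 9 for blood-cell genes. In EpCAM-high they were 22 and 22, 13 and 11, 13 and 12, 11 and 10, and 5 and 4. The gene-end differences at Reep5, Zeb1 (both CK19) and Hmga2 (Sox9) were lost with a window of 2500 bp, which gave the other list a gene-end peak too.

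**Figure D2:**
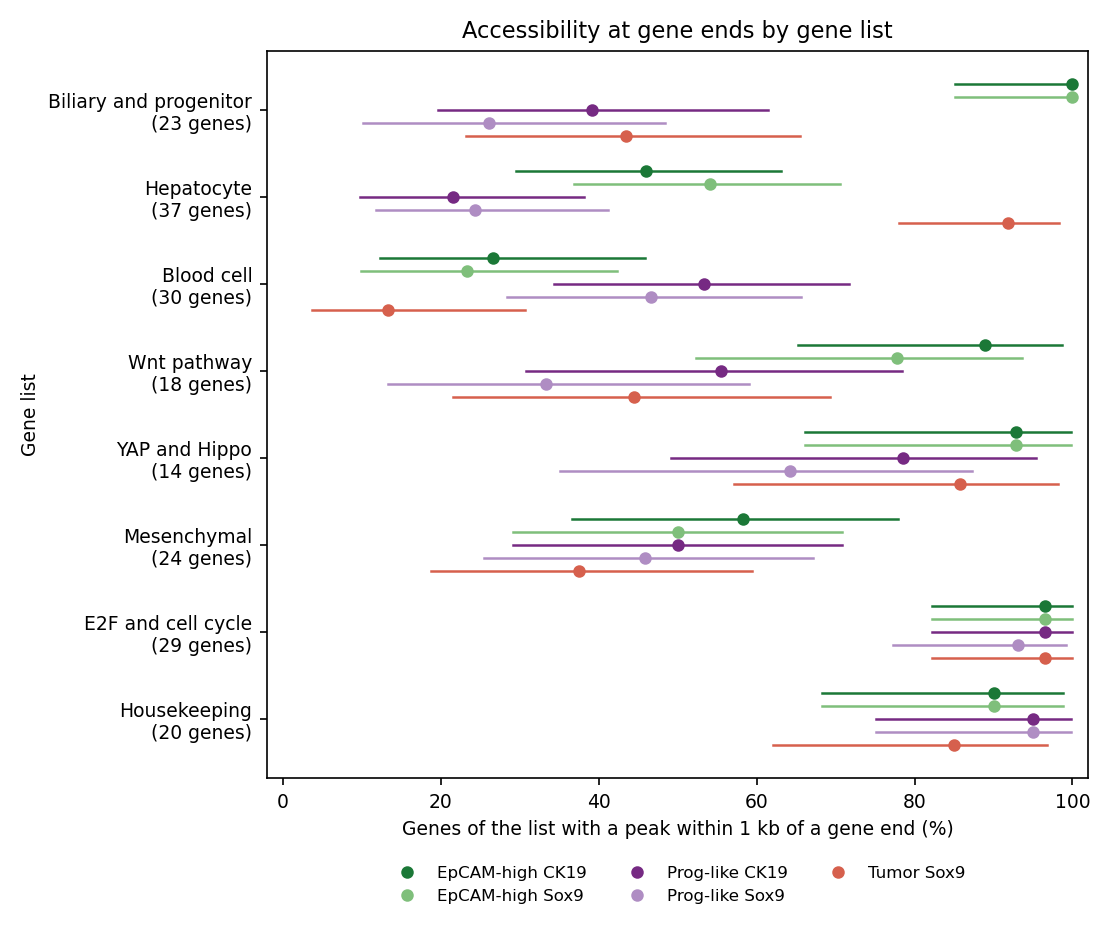
Percentage of the genes of 8 gene lists with a peak within 1 kb of either gene end, in each of the 5 peak lists; points are shares of genes and bars are exact 95% binomial intervals, which cover counting error only. Biliary genes stand at 100% in both EpCAM-high lists, hepatocyte genes at 91.9% in Tumor Sox9, and blood-cell genes at 53.3% and 46.7% in the Prog-like lists.

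The CK19 and Sox9 sets were then compared within the Prog-like lists and within the EpCAM-high lists. The 2 Prog-like lists were the most alike of all pairs, with 74.5% of merged regions held by both (74.2 to 74.8), and 35772 of the 138775 regions in the union of the 5 lists were held by these 2 lists and no other (25.8%). Gene-list members differed little between them: biliary 9 against 6 of 23, hepatocyte 8 against 9 of 37, blood-cell 16 against 14 of 30 and Wnt 10 against 6 of 18 (3 against 3 at equal length). Mesenchymal genes had gene-end peaks at 12 against 11 of 24 members, but their loci held 93 against 74 peaks (33 against 35 at equal length). Only 1 gene of the lists, Zeb1, had a gene-end peak in 1 of the 2 Prog-like lists (Prog-like Sox9) both as deposited and at equal length, with 9 against 8 locus peaks. A window of 2500 bp removed that difference.

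In the Prog-like pair, the genes with the most added peaks at equal length were Itsn1 (19 against 12), Mertk (11 against 5), Itgb5 (16 against 11), Reep3 (14 against 9) and Rere (21 against 16) in the CK19 set. In the Sox9 set they were Mid1 (10 against 2), Thrb (22 against 14), Dpp10 (26 against 19), Pde1a (17 against 10) and Akap13 (23 against 17). The leading region in Prog-like CK19 alone lay in Skint3 (chromosome 4, 112255767 to 112256636; −log10 q 219), followed by regions nearest to Rpe65 and Pls3. In Prog-like Sox9 alone, 2 of the leading 3 regions lay on chromosome Y, in Ddx3y (1285824 to 1286820; −log10 q 151) and in Uty, and the other was nearest to Epha7. A gene-end peak was found in Prog-like CK19 alone at 805 genes and in Prog-like Sox9 alone at 154, with 11754 in both.

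The 2 EpCAM-high lists shared 51.9% of their merged regions (51.6 to 52.3), against 1.1% on average after sliding. Biliary genes had a gene-end peak at all 23 members in both, and their median locus held 1 more peak in the Sox9 set (percentile 4.20). Of the fixed lists, 12 genes had a gene-end peak in 1 of these lists alone at both lengths. In EpCAM-high CK19 these were the Notch ligand gene Dll4 (6 against 3 locus peaks), Hand2 (4 against 2), Lef1 (4 against 2), Tdo2 (2 against 1), Tgfbi (2 against 1), Umod (1 against 0) and Gata3 (2 against 2). In EpCAM-high Sox9 they were the fibrinogen genes Fga (2 against 0) and Fgg (3 against 1), the chemokine gene Cxcl2 (2 against 1), Lcn2 (3 against 2) and Cd68 (3 against 3). Inflammation genes had gene-end peaks at 10 of 20 members in the CK19 list and 13 in the Sox9 list, and hepatocyte genes at 17 and 20 of 37. Blood-cell genes stood at 8 and 7 of 30.

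In the EpCAM-high pair, the genes with the most added peaks at equal length were Dlg2 (32 against 19), Sntg1 (21 against 10), Dmd (19 against 10), Esrrg (24 against 15) and Auts2 (35 against 27) in the CK19 set. In the Sox9 set they were Mcc (22 against 6), Nav2 (22 against 11), Gpc6 (26 against 16), Mecom (13 against 3) and Etl4 (31 against 22). The leading regions of 1 list alone were nearest to Chordc1 (chromosome 9, 17675135 to 17676196; −log10 q 299.98), Olfr103 and Cdk5rap2 for CK19. For Sox9 they lay nearest to Slc39a10 (chromosome 1, 47545341 to 47546141; −log10 q 197), in Runx2 and nearest to Agr3. A gene-end peak was found in EpCAM-high CK19 alone at 654 genes and in EpCAM-high Sox9 alone at 629, with 12002 in both. The order depended on the choice made (893 and 434 at equal length, 706 and 739 with a window of 2500 bp). The same window removed the difference at Dll4, Lef1, Lcn2, Cd68 and Gata3.

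Tumor Sox9 was compared with EpCAM-high Sox9. Hepatocyte genes were accessible in Tumor Sox9, where 34 of 37 members had a gene-end peak (91.9%, 78.1 to 98.3), against 20 in EpCAM-high Sox9 (54.1%, 36.9 to 70.5). The median hepatocyte gene held 1 more peak in Tumor Sox9, above all 10000 random lists (percentile 100). Apoc3 (4 against 1), the fibrinogen gene Fgb (4 against 1), the haptoglobin gene Hp (6 against 3) and the clotting factor gene F9 (3 against 0) had a gene-end peak in Tumor Sox9 alone. Biliary genes had a gene-end peak at 10 of 23 members in Tumor Sox9 (43.5%, 23.2 to 65.5), with 3 fewer peaks at the median gene (percentile 0.0). With a window of 2500 bp the Tumor Sox9 count rose to 15, against 23 in EpCAM-high Sox9. Cftr (1 against 15), Tspan8 (1 against 8), Krt19 (0 against 6), Dmbt1 (0 against 4), Krt7 (0 against 4), Aqp1 (2 against 5) and Krt23 (4 against 7) had a gene-end peak in EpCAM-high Sox9 alone.

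The same held for Reln (1 against 13), Hmga2 (2 against 8), Pdx1 (0 against 6), Wnt7b (1 against 7), Cxcl5 (0 against 4), Sox17 (0 against 4), Il33 (1 against 4) and Kit (0 against 3). Wnt pathway genes had gene-end peaks at 8 of 18 members in Tumor Sox9 and 14 in EpCAM-high Sox9 (median difference at percentile 0.04), Notch genes at 10 and 12 of 16 (percentile 0.205) and YAP and Hippo genes at 12 and 13 of 14. Blood-cell genes stood at 4 and 7 of 30 and endothelial genes at 0 and 2 of 15. At equal length EpCAM-high Sox9 held gene-end peaks at 4 blood-cell, 1 endothelial, 11 Wnt and 17 hepatocyte members, and the Tumor Sox9 counts were unchanged. With a window of 2500 bp blood-cell genes stood at 8 and 11 and endothelial genes at 2 and 4. Afp, the fetal albumin-like gene (chromosome 5, 90490714 to 90508907), held 4 locus peaks in Tumor Sox9 and 1 in EpCAM-high Sox9, with a gene-end peak in neither (in Tumor Sox9 with a window of 2500 bp).

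The genes with the most added peaks at equal length were Lrrc4c (25 against 0), Csmd3 (24 against 1), Lrp1b (24 against 1), Cadm2 (22 against 2) and Cdh18 (18 against 1) in Tumor Sox9. In EpCAM-high Sox9 they were Auts2 (27 against 4), Tenm4 (19 against 0), Etl4 (31 against 13), Rbms3 (23 against 5) and Pde4d (46 against 29). The 113 Tumor Sox9 peaks at its 5 genes had a median of the authors' −log10 q of 2.74, against 8.78 for that whole list. The leading regions of Tumor Sox9 alone were nearest to Hjurp (chromosome 1, 88287433 to 88288665; −log10 q 134), Gpc5 and Olfm3, and those of EpCAM-high Sox9 alone lay in Macrod2 (chromosome 2, 140790343 to 140790781; −log10 q 234), Slco4c1 and Rab27b. Both lists held 33.1% of the merged regions (32.8 to 33.5), against 0.975% on average after sliding. A gene-end peak was found in Tumor Sox9 alone at 562 genes and in EpCAM-high Sox9 alone at 2006, a difference that closed at equal length (1268 and 1262). A window of 2500 bp removed the difference at Wnt7b and Krt23.

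**Figure D3:**
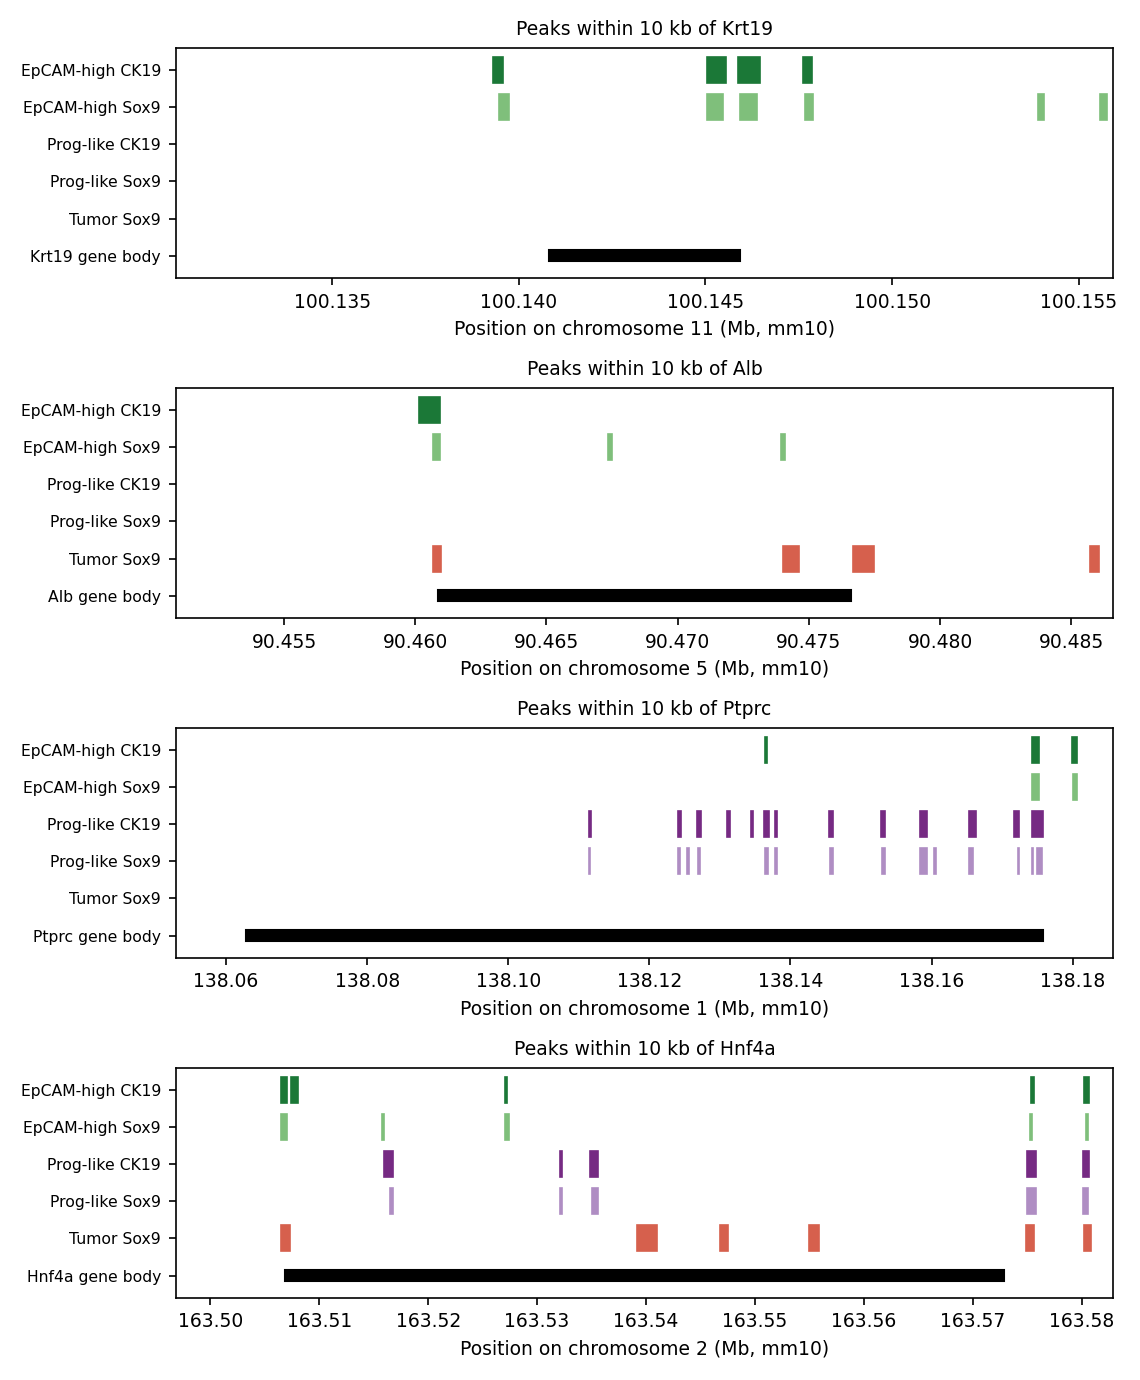
Peaks of the 5 lists (coloured boxes, 1 row per list) within 10 kb of Krt19, Alb, Ptprc and Hnf4a, with the gene body as a black box and mm10 positions in Mb on the horizontal axis. Krt19 has 4 and 6 peaks in the EpCAM-high lists and 0 in the others, and Alb has 4 in Tumor Sox9 and 0 in both Prog-like lists. Ptprc has 13 and 14 in the Prog-like lists and 0 in Tumor Sox9. Hnf4a has 5 or 6 in every list, at partly different positions, with those from 163539144, 163546813 and 163554959 in Tumor Sox9 alone.

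Tumor Sox9 was last compared with Prog-like Sox9, the pair with the smallest share of common regions. Hepatocyte genes had a gene-end peak at 34 of 37 members in Tumor Sox9 against 9 in Prog-like Sox9, with 2 more peaks at the median gene (percentile 100). The genes with a gene-end peak in Tumor Sox9 alone included Ahsg (5 against 0), Hp (6 against 1), Alb (4 against 0), Apoc3 (4 against 0) and the urea cycle gene Ass1 (4 against 0). Others were Bicc1 (9 against 1), Tead1 (8 against 3), Tead4 (5 against 0) and Cdh2 (11 against 1). Blood-cell genes had a gene-end peak at 4 of 30 members in Tumor Sox9 (13.3%, 3.76 to 30.7) against 14 in Prog-like Sox9, and at 8 against 16 with a window of 2500 bp. Ptprc (0 against 14), Adgre1 (0 against 5), Laptm5 (0 against 5) and Lyz2 (0 against 5) were among the genes with a gene-end peak in Prog-like Sox9 alone. So were Zeb2 (4 against 22), the smooth muscle actin gene Acta2 (0 against 8), Vwf (4 against 12), Kdr (0 against 5), Ltbp2 (1 against 8), Lfng (0 against 5) and Actb (2 against 7).

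Biliary genes stood at 10 and 6 of 23, Wnt genes at 8 and 6 of 18, and YAP and Hippo genes at 12 and 9 of 14 in Tumor and Prog-like Sox9. At equal length the Prog-like counts fell to 2, 3 and 6, and those of hepatocyte and blood-cell genes to 5 and 9. The genes with the most added peaks at equal length were Lrrc4c (25 against 0), Csmd3 (24 against 0), Lrp1b (24 against 1), Ptprd (23 against 0) and Tenm3 (23 against 0) in Tumor Sox9, whose peaks there had a median −log10 q of 3.11. In Prog-like Sox9 they were Tenm4 (26 against 0), Maml2 (27 against 2), Zfhx3 (34 against 10), Hdac9 (25 against 2) and Med12l (25 against 2). The leading regions of Tumor Sox9 alone were nearest to Gpc5 (chromosome 14, 114062605 to 114063149; −log10 q 125) and in Bche and Xkr4, and those of Prog-like Sox9 alone were the same regions at Aga, 1700017N19Rik and Cacna2d1 that EpCAM-high Sox9 lacked. Both lists held 17.9% of the merged regions (17.7 to 18.2), against 1.07% on average after sliding.

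Of the 39644 Tumor Sox9 peaks, 14495 overlapped a peak in both other Sox9 lists (36.6%, 36.1 to 37.0), 9968 in EpCAM-high Sox9 alone (25.1%, 24.7 to 25.6), 1951 in Prog-like Sox9 alone (4.92%, 4.71 to 5.14) and 13230 in neither (33.4%, 32.9 to 33.8). At equal length these 4 shares were 28.6%, 23.6%, 4.56% and 43.2%. As deposited, 59.8% of the peaks found in all 3 Sox9 lists lay at gene ends, against 5.06% of those found in Tumor Sox9 but in neither other list. A gene-end peak was found in Tumor Sox9 alone at 1181 genes and in Prog-like Sox9 alone at 1902, and this order turned at equal length (2208 and 1061). The difference at Actb was lost with a window of 2500 bp.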

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

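The tests of list length, of a small share of blood cells and of hepatocytes outside tumours were chosen after the values they concern had been seen, and those of macrophage genes and of chromosome Y genes before. The choice of which gene-list sums and named genes to compare between the CK19 and Sox9 sets was also made after seeing the data.

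Mesenchymal genes held more locus peaks in Prog-like than in EpCAM-high in the CK19 set (93 against 70, a difference of 23) and fewer in the Sox9 set (74 against 75, a difference of -1). Cancer stem cell genes moved apart in the same way (58 against 48, a difference of 10, and 48 against 55, a difference of -7), as did Pkhd1, a gene of bile duct cilia (13 against 4, a difference of 9, and 7 against 8, a difference of -1). At equal length these divergences went: mesenchymal genes held 33 against 45 in the CK19 set and 35 against 43 in the Sox9 set, cancer stem cell genes 31 against 38 in both, and Pkhd1 4 against 4 and 0 against 3. None of these differences between the sets was tested further, since each rests on 1 list per condition. Peaks on unplaced or unlocalised contigs, which no gene comparison used, numbered 99 in EpCAM-high CK19, 68 in EpCAM-high Sox9, 113 in Prog-like CK19, 100 in Prog-like Sox9 and 89 in Tumor Sox9.

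The Prog-like lists held gene-end peaks at more blood-cell genes and fewer biliary genes than the EpCAM-high lists. List length was a poor explanation, since at equal length the excess of blood-cell members was 5 of 30 in the set where it was smaller. A small share of blood cells in an otherwise EpCAM-high-like population would have left a gene-end peak at most of the 23 biliary genes, and at most 9 had one in a Prog-like list. Cells with macrophage-type accessibility remain a candidate source: of 20 macrophage genes, a list prompted by the blood-cell result but predicted before its own values were seen, 18 had a gene-end peak in each Prog-like list against 3 and 4 in the EpCAM-high lists, and the excess at equal length was at least 70.0 percentage points. Sorting for YFP should remove most such cells. The Thy1 and EpCAM gate behind the Prog-like lists is unknown, since they were tied to no sorted group. The labels include EpCAM-negative cells, but name no CK19 or Sox9 set for them, whereas the Thy1-positive groups have both. Liver macrophages may have passed the sort, through autofluorescence or Cre activity, or recombined cells may have taken on a macrophage-like state. Which of these holds stays open and was not tested. Endothelial genes, too, held more locus peaks at equal length, 40 and 41 in Prog-like CK19 and Sox9 against 25 and 26 in EpCAM-high. The Prog-like excess was thus not confined to macrophage genes, and other cell sources were not tested.

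Tumor Sox9, the shorter list (39644 against 59454 peaks), held gene-end peaks at more hepatocyte genes than EpCAM-high Sox9 (34 against 20 of 37). Tumour cells of hepatocyte type and hepatocytes outside tumours both predict peaks at these genes, of which 34 had one, and peak lists alone cannot tell them apart. Sorting for YFP should remove hepatocytes in which Cre did not act, but recombined hepatocytes outside tumours would pass. A biological difference between the cells of these lists stays open and untested.

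Chromosome Y peaks numbered 1 in EpCAM-high CK19 and 0 in Prog-like CK19, against 10 in EpCAM-high Sox9, 22 in Prog-like Sox9 and 17 in Tumor Sox9. Of Ddx3y, Kdm5d, Uty and Eif2s3y, 4 had a gene-end peak in Prog-like Sox9 and in Tumor Sox9, 3 in EpCAM-high Sox9 (all but Kdm5d) and 0 in both CK19 lists. Animals of different sex are a possible explanation. The prediction of all 4 genes in each Sox9 list was missed by the value of 3. The outcome set against it, 2 or more of the 4 missing in a Sox9 list or any present in a CK19 list, was not met either. The explanation therefore stays open. The X-linked gene Xist held 3 and 4 locus peaks in the CK19 lists and 0, 1 and 2 in EpCAM-high, Prog-like and Tumor Sox9, with a gene-end peak in Prog-like CK19 alone. Any difference between the CK19 and Sox9 sets may therefore include one between the sexes, which the labels do not give.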

How the results depend on the processing

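The alternatives for shared regions and gene-end counts were fixed before the data were examined, and the mean differences of gene lists were added after they were seen. No paired analysis was possible because each condition has 1 peak list and none per sample, so no replicate could be left out either; the motif scan, its alternative window and the split of exons and introns were not run. The order of the 6 pairs by shared regions stayed the same under all 4 alternatives. With lists of equal length the shares were 61.9% (EpCAM-high CK19 and Sox9), 81.2% (Prog-like CK19 and Sox9), 21.9% (Prog-like and EpCAM-high CK19), 20.9% (Prog-like and EpCAM-high Sox9), 19.7% (Tumor and Prog-like Sox9) and 35.4% (Tumor and EpCAM-high Sox9). With −log10 q of 5 or more they were, in that order, 60.7%, 78.9%, 21.0%, 19.6%, 18.6% and 37.0%, and with an overlap of 50% they were 51.5%, 19.5%, 18.6%, 17.4% and 32.6% for all pairs but the Prog-like one, which stayed within its interval. Autosomes alone left all 6 within their intervals. Of 48 counts of genes with a gene-end peak in 1 list alone, 44 stayed within 1.5 times, and 4 did not, all at equal length: 2208 and 1061 for Tumor and Prog-like Sox9, 1268 and 1262 for Tumor and EpCAM-high Sox9. Shortening the longer list removes its weakest peaks, which is how that setting is built; other causes were not tested.

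Mean differences in locus peaks of lists beyond percentiles 2.5 or 97.5 changed sign in 3 cases: hepatocyte genes in Prog-like against EpCAM-high CK19 with 50 kb flanks (0.486), mesenchymal genes in Prog-like CK19 against Sox9 at equal length (-0.0833) and YAP and Hippo genes in Tumor against Prog-like Sox9 at equal length (1.07); the cause was not tested. Over all lists, 253 of 306 values kept their sign and 132 moved by at most 50%. Of 255 member counts, 228 stayed within 1.5 times, and the 27 others were lower (19, equal length) or higher (8, window of 2500 bp). All 93 named gene-end differences held at the stricter threshold and 80 with the wider window. Depth, which is unknown, limits any reading of a missing peak as closed chromatin.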

Other observations

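The macrophage, T and NK, B and plasma, neutrophil, dendritic, and erythroid and megakaryocyte lists were added after the first results, and the other lists were fixed before the data were examined. Genes of liver-resident macrophages had a gene-end peak at 18 of 20 members in each Prog-like list. Clec4f, a lectin gene of Kupffer cells (chromosome 6, 83644542 to 83656116), held 6 and 7 locus peaks in Prog-like CK19 and Sox9 and 0 in the other 3 lists. Vsig4 (14 and 11), Timd4 (11 and 14), Marco (7 and 7) and the complement genes C1qa (5 and 5) and C1qb (5 and 4) also held 0 in the other 3 lists. These genes were chosen after their values were seen. The 20 macrophage genes held 156 and 158 locus peaks in the Prog-like lists, 13 and 17 in EpCAM-high CK19 and Sox9 and 13 in Tumor Sox9, and none of them is in a list fixed before. T and NK genes had gene-end peaks at 6 and 5 of 14 members in the Prog-like lists against 3 and 4 in the EpCAM-high lists and 2 in Tumor Sox9, and B and plasma cell genes at 5 and 4 of 12 against 3 and 4, and 3. Neutrophil genes stood at 2 and 2 of 11 against 1 and 1, and 0, dendritic genes at 4 and 3 of 8 against 4 and 3, and 2, and erythroid and megakaryocyte genes at 4 and 4 of 9 against 2 and 3, and 3. At equal length macrophage genes held 90 and 84 locus peaks in the Prog-like lists against 8 and 10 in the EpCAM-high lists. There T and NK genes had gene-end peaks at 4 and 3 members against 3 and 3, and B and plasma cell genes at 3 and 3 against 3 and 1. Neutrophil genes held 21 and 21 locus peaks against 3 and 5 at equal length, and dendritic genes 20 and 20 against 7 and 8. B and plasma cell genes held 24 and 21 against 15 and 12, and T and NK genes 18 and 16 against 20 and 16. Erythroid and megakaryocyte genes held 7 and 9 against 9 and 10. The excess in locus peaks was thus not confined to macrophage genes.

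Oncofetal genes, which are used in fetal liver and again in liver cancer, had gene-end peaks at 8, 8, 8, 6 and 6 of 15 members in EpCAM-high CK19, EpCAM-high Sox9, Prog-like CK19, Prog-like Sox9 and Tumor Sox9. At equal length they were 8, 8, 4, 3 and 6. Cancer stem cell genes stood at 8, 9, 7, 6 and 6 of 13 in the same order, the Rb family at 3, 2, 3, 2 and 2 of 3, and the 2 sort markers at 1 in each list (0 in both Prog-like lists at equal length). Mesenchymal genes stood at 9 of 24, TGF-beta genes at 9 of 15 and inflammation genes at 11 of 20 in Tumor Sox9. Genes of other tissues, a group not tied to liver, had gene-end peaks at 5, 4, 3, 3 and 3 of 20 (4, 3, 2, 1 and 3 at equal length, 6, 6, 6, 5 and 4 with a window of 2500 bp). Afp had a gene-end peak in the 2 Prog-like lists alone, with 3 and 2 locus peaks, although its locus held 4 in Tumor Sox9, where a window of 2500 bp also gave a gene-end peak. At equal length Afp had no gene-end peak in any list, and its locus held 0 and 1 peaks in Prog-like CK19 and Sox9. In the union of all lists, 13529 regions were held by all 5 (9.75%), 12938 by the 2 EpCAM-high lists and no other (9.32%) and 11720 by Tumor Sox9 alone (8.45%). The last share depended on Tumor Sox9 being the shortest list, and at equal length it was 16.7% (15132 regions).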
